A study of Mus musculus with 4 samples.

How the data were processed

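Gene expression was measured by RNA sequencing in mouse 3T3 cells that received control treatment or recombinant LTα1β2 for 24 h or 48 h. There were 4 groups and 1 library in each. Per the labels' protocols, total RNA was isolated with RNAiso Plus. Libraries were made from 1 µg of it with a kit that keeps the strand of the RNA, and were sequenced as 150 bp read pairs on a NovaSeq. The aligner, the read counter, the genome build and the annotation are not given in the sources used here. Whether counting used the strand is not given either. Per the submitters' processing notes, edgeR 3.30.0 was among the tools used.

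The authors deposited 1 table of CPM (counts per 1000000) for 12208 genes under versioned Ensembl identifiers, with 1 column per library. Each CPM column as deposited sums to 1000000, so the totals were taken over the listed genes and not over all reads. The table holds no zeros. The lowest value corresponds to 9 to 12 reads depending on the library, so genes silent in any of the 4 libraries are not analysed here. A gene that treatment switched on from no reads, or off to no reads, would therefore be missed. The usual step between the lowest CPM values, refined by least squares, gave the worth of 1 read in each library, and 100% of the values in each column were whole multiples of it within 0.01 of a read. The totals recovered in this way were 15995777 reads for control at 24 h, 13097396 for control at 48 h, 14986101 for LTα1β2 at 24 h and 11355974 for LTα1β2 at 48 h. These reads were used for exact 95% intervals (conditional binomial, Clopper-Pearson) of the ratio of CPM between 2 libraries. The intervals cover counting error only and not the differences between cultures. No column of the table was left out.

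Gene symbols and transcript lengths came from GENCODE M21 (GRCm38), in which 12205 of the 12208 identifiers were found when versions were ignored and 11716 with the version. Log2 folds are differences of log2(CPM + 1), which understates the change of low genes. Genes with a mean CPM of at least 1 over the 4 libraries were tested, which left 12160. With 1 library per group there was no test of treatment at 1 time or of time in 1 treatment. A gene was counted there by a rule of size, at least 2-fold, with no p-value. The count of genes passing at both times was set beside the overlap of independent lists (n1 × n2 / N per direction). These comparisons share no library.

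The only test was an additive model of time and treatment in limma 3.58.1 (R 4.3.3, trended empirical Bayes, two-sided, Benjamini-Hochberg 0.05). It treats 24 h and 48 h as repeats of the treatment and has 1 residual degree of freedom. The estimated prior degrees of freedom were infinite, so each gene was given the spread typical of its level and not its own. Its p-values set a gene's mean difference against how far the 24 h and 48 h differences typically lie apart in genes of like level, so a gene whose own differences lie far apart can pass. Nothing says that the libraries came from separate experiments. "Rose" and "fell" are used only of genes past this test or, where the text says so, past another limma fit or another adjustment. On simulated reads of the 12160 genes with an assumed dispersion of 0.005, the additive fit recovered 52 of 67 genes changed 1.5-fold (77.6%), 64 of 67 changed 2-fold (95.5%) and 66 of 66 changed 4-fold (100%), with 6 false calls among 188. The simulation held no difference in transcript length between libraries, no effect of time and the same treatment fold at both times. The spread in this fit is the difference between the folds at the 2 times, so these rates need not hold for the data.

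There were 29 gene lists, fixed before the data were examined, as were the tests of the comparisons, the rule for named genes and the settings listed first below. Tests of explanations in the closing section were set later. For each list with at least 3 tested members the median log2 fold was set against 10000 random lists of equal size matched on mean expression in 20 bins. Its percentile describes these libraries and is no test. Named genes were the 10 highest and 10 lowest by mean fold among genes changed 2-fold at both times, and the 5 highest and 5 lowest folds at each time. Up to 4 members of each list with the largest mean fold were added, as were Ltbr, Nfkb2, Relb, Ccl2, Ccl5, Tnfsf11 and Tnfrsf11b always. For time, the 6 highest and 6 lowest genes changed 2-fold in both treatments could be named. Gene models without an informative symbol were counted but not named under the first, second and last parts of the rule. Tnfsf11 was not among the tested genes. Genes named outside the rule are said to be so.

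The other settings were pseudocounts of 0.25 and 5, no filter on low values, a mean CPM of at least 5, a threshold of 1.5-fold, median-of-ratios rescaling of the columns, rescaling without mitochondrial genes, a fit with no time term and a fit with no trend. Settings chosen after seeing the data were the removal of each library's trend on transcript length, leaving out each library in turn (treated against control with no time term, since 3 libraries cannot hold one), limma voom on the recovered reads, and other prior degrees of freedom. These were infinite ones for the fits with median-of-ratios rescaling, with the length trend removed and with no time term (estimated there as 9.8, 11.1 and 6.3), and 9.8 for the additive fit, which lets each gene's own spread count. The trend was a running median over 40 bins of the longest annotated transcript's length, which was known for 99.98% of the tested genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.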

Results

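The transcriptome of 3T3 cells, given in the labels as a mouse pre-osteoblast line, was compared between control cells and cells treated with recombinant LTα1β2 for 24 h or 48 h. The name 3T3 is also that of fibroblast lines, and which line was used is not settled here. LTα1β2 is the membrane-type lymphotoxin of the TNF superfamily, and its receptor, the lymphotoxin β receptor encoded by Ltbr, signals through NF-κB. Each of the 4 groups was 1 library, so no difference at a single time has a replicate check. Depth, as reads recovered from the CPM values, was 15995777 (control, 24 h), 13097396 (control, 48 h), 14986101 (LTα1β2, 24 h) and 11355974 (LTα1β2, 48 h). Ltbr was expressed in every library, at 156 and 150 CPM in control and 151 and 130 CPM in treated cells at 24 h and 48 h. Across genes, log2(CPM + 1) correlated most closely between the control libraries (Pearson's r = 0.9952), and the treated 24 h library lay near them (0.9923 with its control). The treated 48 h library stood apart, with r from 0.9735 to 0.9816 to the other libraries. Its read-weighted median transcript length was 3127 bases, against 3659 and 3595 in control at 24 h and 48 h and 3589 in treated cells at 24 h. Genes are not independent replicates, so no p-value is given for these correlations.

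Which genes differed with treatment at both times was asked first, since the comparison at 24 h and that at 48 h share no library. Chemokine genes, complement C3, the gelatinase gene Mmp9 and genes of NF-κB feedback were higher in treated cells at both times, while the osteoblast transcription factor gene Sp7 and several matrix and Wnt genes were lower. C3 went from 42.9 to 325 CPM at 24 h (7.59-fold, 95% counting interval 7.0 to 8.23) and from 42.1 to 393 CPM at 48 h (9.34-fold, 8.54 to 10.2). Mmp9 was 8.35-fold higher at 24 h (7.14 to 9.81) and 7.06-fold higher at 48 h (6.21 to 8.06). Serpina3g, a serine protease inhibitor gene of a family of closely similar copies whose reads can be shared, was 7.55-fold and 7.27-fold higher. Slfn2, a schlafen family gene, was 2.40-fold and 5.72-fold higher. Among the lower genes, Npnt, which encodes the matrix protein nephronectin, fell to 0.426 of control at 24 h (0.385 to 0.472) and 0.129 at 48 h (0.110 to 0.151). Sp7 was at 0.365 (0.308 to 0.430) and 0.257 (0.202 to 0.324) of control. Cyp26b1, which encodes a retinoic acid-degrading enzyme, was at 0.324 and 0.297 of control. Igfbp5, an IGF-binding protein gene, was at 0.373 and 0.227, Mest at 0.396 and 0.242, and Tnfrsf19, a TNF receptor family gene, at 0.421 and 0.162. Prlr, Shank1, Thsd4 and Insc completed the 10 genes lowest by mean fold, with log2 folds from -1.22 to -1.01 at 24 h and from -1.56 to -1.13 at 48 h.

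**Figure D1:**
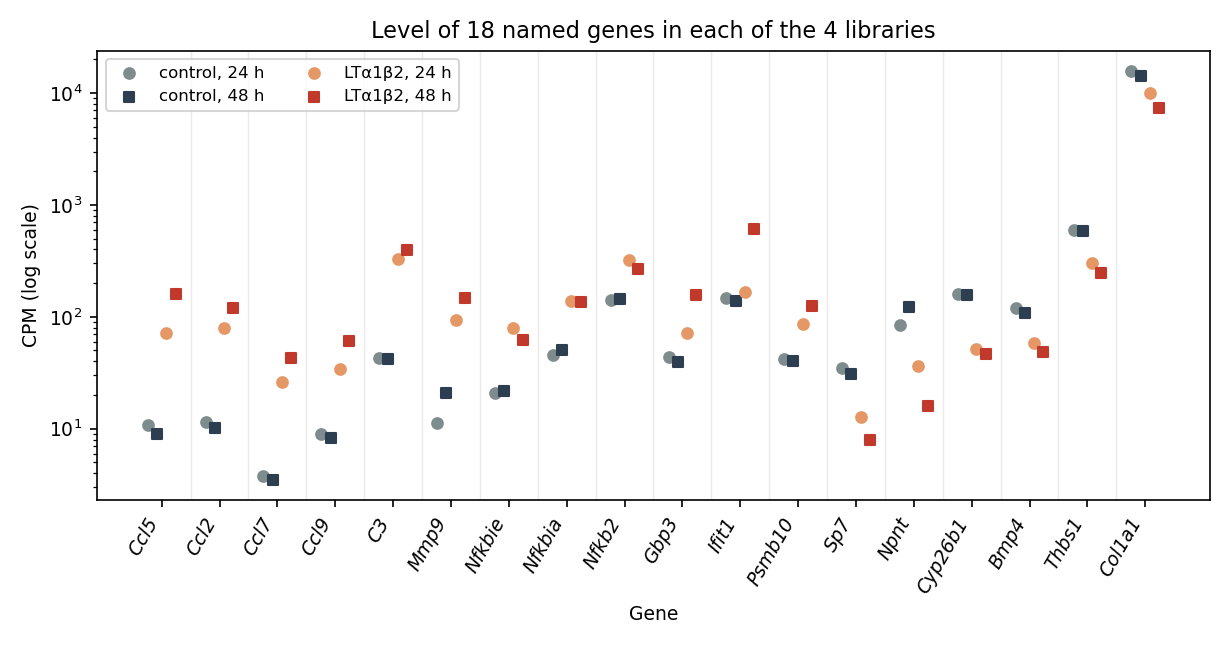
CPM on a log axis of named genes in each of the 4 libraries, 1 point per library, circles for 24 h and squares for 48 h, grey and dark for control and orange and red for LTα1β2. C3 lay at 42.9 and 42.1 CPM in the control libraries and at 325 and 393 CPM in the treated ones, while Ifit1 stood apart in the treated 48 h library only, at 603 CPM.

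By the 2-fold rule, 26 genes were higher and 13 lower at both times, where independent lists would share 0.781 and 0.157, and 0 genes passed in opposite directions. Removing each library's transcript-length trend left 23 of the 26 and 11 of the 13 on the list. Across the 12160 genes the folds at 24 h and 48 h correlated with Pearson's r = 0.487 and Spearman's rho = 0.418. In the additive fit 355 genes rose and 276 fell at an adjusted p of 0.05 (limma), all 39 genes above among them. Of these 631 genes, 625 had folds of 1 sign at both times. The 39 and the 625 follow largely from the choice of genes. A gene 2-fold changed at both times has a large mean fold, and a large mean fold favours 1 sign. The additive fit gave every gene the spread typical of its level (infinite prior degrees of freedom). With 9.8 prior degrees of freedom, so that a gene's own spread counts, it gave 39 and 25, and 64 of the 631 were called. Without a time term the 4 libraries gave 20 and 11, and 403 and 320 with infinite prior degrees of freedom. With 3 libraries no time term can be held, so leaving a library out also drops it. Such fits gave 402 and 370 without the treated 48 h library, with 344 of the 631 also called, 1886 and 3063 without the treated 24 h library, 23 and 8 without the 24 h control, and 16 and 6 without the 48 h control. List counts given without the treated 48 h library come from the first of these and have no time term either. That fit sets the treated 24 h library against the mean of both controls, so changes with time in control enter its folds. Median-of-ratios rescaling gave 95 and 83, and 178 of the 631 were called there too; the prior degrees of freedom were then estimated as 9.8, and with infinite ones it gave 809 and 459, with 629 of the 631. Length-trend removal gave 367 and 305, with 425 of the 631, at an estimated 11.1, and 1044 and 709, with 602 of the 631, at infinite ones. List counts under these settings are at infinite prior degrees of freedom, as in the additive fit, unless said otherwise.

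**Figure D2:**
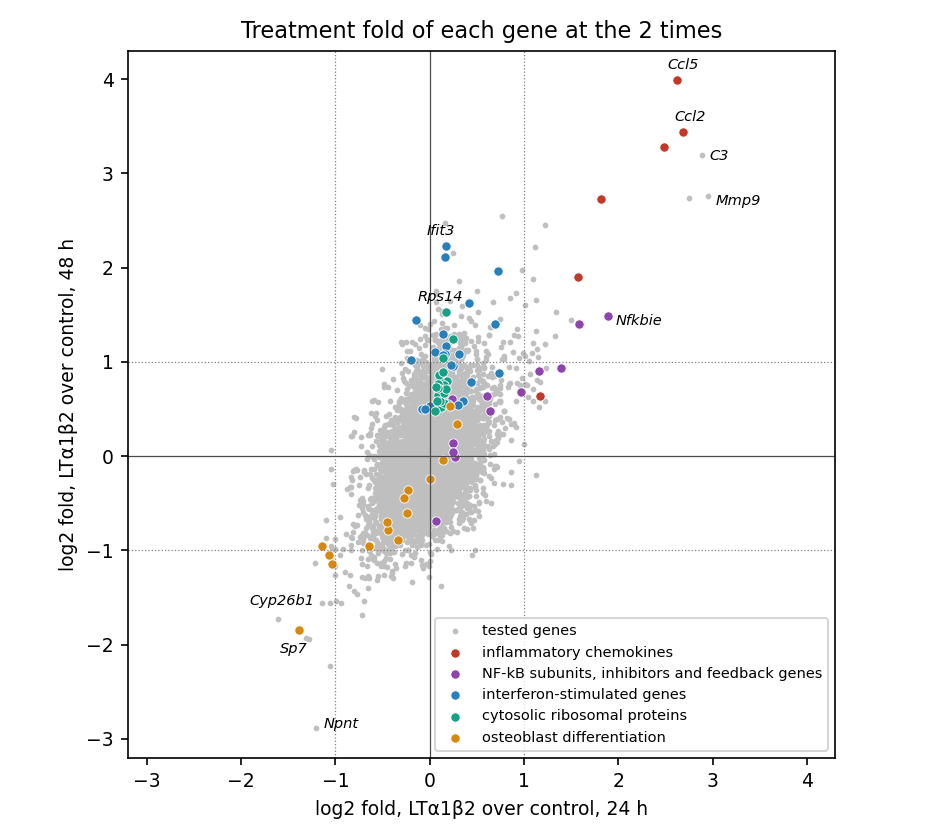
Log2 fold of LTα1β2 over control at 24 h (x axis) and 48 h (y axis) for each tested gene, with 5 gene lists in colour and dotted lines at 2-fold. Chemokine genes lie high on both axes, most osteoblast genes low on both (12 of 15 below 0 at both times, 2 above), and interferon-stimulated and ribosomal protein genes are shifted mainly along the 48 h axis (list medians 0.17 and 1.02, and 0.12 and 0.73).

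At 24 h alone, 42 genes were at least 2-fold higher and 22 at least 2-fold lower in treated cells. The highest folds were those of Mmp9, C3, Serpina3g, Ccl2 and Ccl5, with log2 folds from 2.62 to 2.95, and the lowest those of Cyp26b1, Sp7, Igfbp5, Mest and Prlr, from -1.61 to -1.22. Nfkb2, which encodes the p100 precursor of non-canonical NF-κB signalling, was at 142 CPM in control and 320 CPM in treated cells (2.25-fold, 2.14 to 2.36). Of the 42 higher genes 41 were also above 0 at 48 h, and of the 22 lower genes 21 were below 0. Folds at 24 h had almost no relation to transcript length across genes (Spearman's rho = -0.023).

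At 48 h alone, 226 genes were at least 2-fold higher and 87 lower in treated cells. The highest log2 folds were 3.99 for Ccl5, 3.44 for Ccl2, 3.28 for Ccl7, 3.19 for C3 and 2.76 for Mmp9. The lowest were -2.88 for Npnt, -2.23 for Tnfrsf19, -1.94 for Mest, -1.93 for Igfbp5 and -1.84 for Sp7. Nfkb2 was 1.87-fold higher (1.77 to 1.98). Of the 226 higher genes 199 were also above 0 at 24 h, and of the 87 lower genes 83 were below 0. Folds at 48 h declined with transcript length (rho = -0.444): the median log2 fold was 0.35 in the 1216 genes with the shortest transcripts and -0.34 in the 1216 with the longest, and 103 of the 226 higher genes lay among the shortest. With the length trend removed the counts were 158 and 66, and with median-of-ratios rescaling 312 and 61, so that the higher genes were 83.6% of the total against 72.2%.

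**Figure D3:**
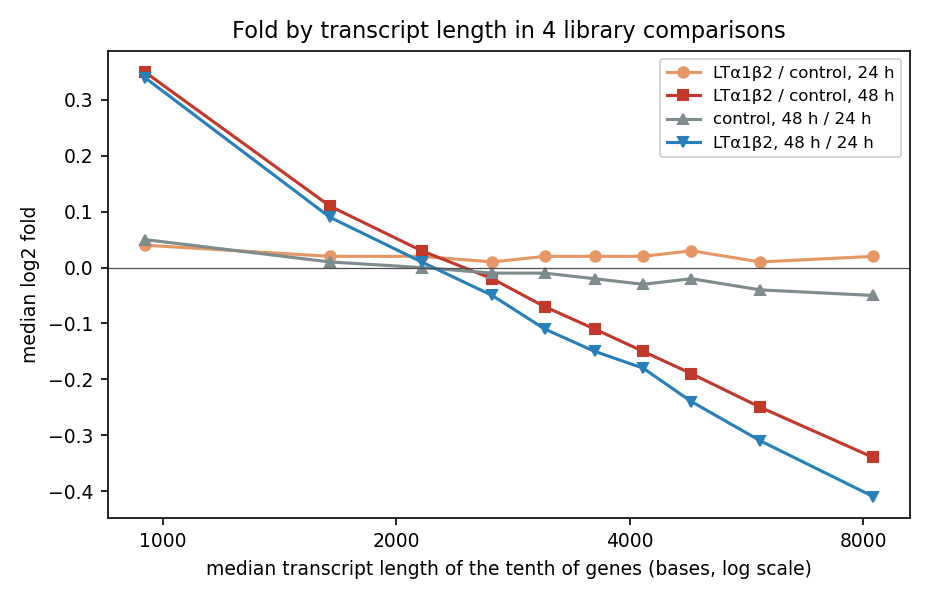
Median log2 fold in 10 groups of genes of rising transcript length (x axis, bases, log scale) for LTα1β2 over control at 24 h and at 48 h, and for 48 h over 24 h in control and in treated cells. Comparisons with the treated 48 h library run from 0.35 and 0.34 in the shortest group to -0.34 and -0.41 in the longest, while LTα1β2 over control at 24 h stays between 0.01 and 0.04.

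Inflammatory chemokine genes had the highest median of the lists at both times. All 6 tested inflammatory chemokine genes (of 18 listed) rose, likewise 6 adjusted over the list alone, with a median log2 fold of 2.15 at 24 h and 3.01 at 48 h against a random range of -0.14 to 0.18 and -0.37 to 0.28. Ccl5, a T-cell and monocyte attractant, went from 10.9 to 72.3 CPM at 24 h (6.64-fold, 5.66 to 7.84) and from 9.01 to 158 CPM at 48 h (17.6-fold, 14.6 to 21.4). Its transcript is short, 668 bases, and its 48 h log2 fold was 3.56 with the length trend removed. Ccl2, the monocyte attractant, was 6.90-fold (5.91 to 8.11) and 11.8-fold higher (9.86 to 14.2), and Ccl7 6.82-fold and 12.2-fold. Ccl9 was 3.81-fold and 7.31-fold higher and Cxcl10, a ligand of CXCR3, 3.22-fold and 4.01-fold. The sixth member, Cx3cl1, named outside the rule, was 2.27-fold higher at 24 h (2.16 to 2.38) and 1.56-fold at 48 h (1.47 to 1.65). In GRCm38 as annotated by GENCODE M21, which may not be the build the authors used, Ccl2 (chromosome 11, 82035571 to 82037453, plus strand) lies beside Ccl7 (82045712 to 82047525, plus strand). Ccl5 (83525778 to 83530518) and Ccl9 (83572919 to 83578636) lie on the minus strand of the same chromosome.

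Of 12 tested genes of NF-κB subunits, inhibitors and feedback, 7 rose and 0 fell, 8 and 0 adjusted over the list alone, with medians of 0.62 and 0.63. Nfkbie and Nfkbia, which encode IκB inhibitors, were 3.84-fold and 3.03-fold higher at 24 h and 2.88-fold and 2.67-fold at 48 h, and Birc3 was 2.80-fold and 1.97-fold higher. Relb, the partner of p100, was 1.55-fold (1.37 to 1.76) and 1.59-fold higher (1.37 to 1.84; limma log2 fold 0.63 ± 0.18 SE, adjusted p = 0.0114). In the lymphotoxin receptor pathway 2 of 12 rose, 4 adjusted over the list alone, and over all genes 5 without the treated 48 h library and 6 with the length trend removed. They were Birc2 (1.88-fold and 2.20-fold) and Map3k14, which encodes the kinase NIK (1.69-fold and 1.68-fold). The receptor gene Ltbr gave log2 folds of -0.04 and -0.21 (adjusted p = 0.808, limma). Of 5 tested lymphoid-tissue stromal genes 2 rose, 5 both adjusted over the list alone and with the length trend removed, and 4 without the treated 48 h library. These 2 were adhesion molecule genes, Vcam1 (1.66-fold and 1.49-fold) and Icam1 (3.08-fold and 3.35-fold, from about 1 CPM in control). Of 9 tested cytokine and acute-phase genes 4 rose, 6 adjusted over the list alone, among them C3, Ptx3 (1.49-fold and 1.51-fold) and Il34 (1.51-fold and 1.97-fold). With the length trend removed at its own estimate of prior degrees of freedom, 4 lymphotoxin receptor pathway genes and 4 lymphoid-tissue stromal genes rose.

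Most tested genes of the osteoblast and matrix lists were lower. Of 15 tested osteoblast differentiation genes 7 fell and 0 rose, 9 and 0 adjusted over the list alone, with medians of -0.34 at 24 h and -0.70 at 48 h (percentile 0 among random lists at both times). Besides Sp7, Bmp4 went from 121 to 58.3 CPM at 24 h (0.484 of control, 0.446 to 0.524) and from 108 to 48.3 CPM at 48 h (0.448, 0.406 to 0.495). Omd, osteomodulin, was at 0.468 and 0.475 of control, and Dmp1, a matrix protein gene of mineralising cells, at 0.393 and 0.483. Runx2 and Col1a1, chosen after their values were seen because of their place in the lineage, were at 0.788 and 0.640 of control at 24 h and at 0.538 and 0.518 at 48 h. Bglap and Bglap2, also named outside the rule, did not pass. Their log2 folds were 0.14 and -0.04 (Bglap, at 1.33 CPM or less in every library) and -0.23 and -0.36 (Bglap2). In the list 12 genes were lower and 2 higher at both times. Without the treated 48 h library 6 of the list fell, and with the length trend removed 6.

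Of 19 tested fibrillar matrix genes 7 fell and 0 rose, 13 and 0 adjusted over the list alone, with medians of -0.35 and -0.72, the latter -0.45 with the length trend removed. The type XI and III collagen genes Col11a1 and Col3a1 were at 0.548 and 0.695 of control at 24 h and at 0.381 and 0.515 at 48 h, and Thbs1, thrombospondin, was at 0.50 and 0.416. Transcripts of this list are long, with a median of 5848 bases, and without the treated 48 h library 9 of its genes fell. Of 9 tested Wnt targets and antagonists 6 fell and 0 rose, 7 and 0 adjusted over the list alone, with medians of -0.62 and -0.84. Sfrp2, a secreted antagonist, went from 438 to 261 CPM at 24 h and from 453 to 249 CPM at 48 h, and the ligand genes Wnt10b and Wnt4 were at 0.641 and 0.439 of control at 24 h and at 0.471 and 0.488 at 48 h. Of 13 TGF-β and YAP targets 3 fell and 0 rose, 5 and 0 adjusted over the list alone, 5 and 2 with the length trend removed and 2 and 2 without the treated 48 h library. The 3 were Myl9, Ccn1 and Acta2, with limma log2 folds of -0.63, -0.59 and -0.61. Of 15 matrix proteases and inhibitors 2 rose, Mmp9 and Timp1, and 2 fell, Adamts1 and Timp3 (2 and 6 adjusted over the list alone, as with the length trend removed). Of 17 cholesterol synthesis genes 1 fell, Fdps, 4 adjusted over the list alone and 8 with the length trend removed. The list medians were -0.23 at 24 h and -0.40 at 48 h. A count without the treated 48 h library is not given for this list. Its genes changed with time in control (median log2 change 0.23), which enters the folds of that fit. With the length trend removed at its own estimate of prior degrees of freedom, 4 cholesterol synthesis genes fell. There 4 TGF-β and YAP targets fell and 1 rose, and 4 matrix proteases and inhibitors fell and 1 rose.

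Interferon-stimulated genes were higher mainly at 48 h. Their median log2 fold over 25 genes was 0.17 at 24 h (random range -0.05 to 0.1), with 0 genes at 2-fold. It was 1.02 at 48 h (-0.25 to 0.06), with 13 at 2-fold. Of the 25 genes, 20 were higher at both times and 0 lower at both. Ifit3 and Ifit1, antiviral effector genes, were 1.13-fold (1.06 to 1.19) and 1.12-fold higher at 24 h (1.06 to 1.18), and 4.72-fold (4.46 to 5.0) and 4.33-fold at 48 h (4.12 to 4.57). The GTPase genes Gbp3 and Gbp2 were 1.66-fold and 1.62-fold higher at 24 h and 3.97-fold and 2.66-fold at 48 h. In the additive fit 16 of the 25 rose and 0 fell, 21 and 0 adjusted over the list alone, but 8 rose without the treated 48 h library. With median-of-ratios rescaling 20 rose, at a 48 h median of 1.10. With 9.8 prior degrees of freedom 2 rose in the additive fit, and Ifit1 and Ifit3, whose folds differ between the times, had adjusted p-values of 0.22 and 0.212 (limma). All 15 antigen presentation genes were higher at both times, with medians of 0.41 and 0.91; 9 rose, 12 adjusted over the list alone and 11 without the treated 48 h library. Psmb10, an immunoproteasome subunit gene, was 2.03-fold and 3.07-fold higher, Cd74, the invariant chain gene, 2.67-fold and 4.04-fold, and Psmb9 1.38-fold and 2.39-fold. The difference between the 24 h and 48 h folds of these lists was not tested. Median-of-ratios rescaling gave counts of 10 for antigen presentation, 6 for osteoblast differentiation, 9 for fibrillar matrix, 6 for Wnt, 5 for cytokines and 7 for NF-κB genes. With its own estimate of 9.8 prior degrees of freedom the counts were 4, 4, 3, 3, 2 and 5, and 3 for interferon-stimulated genes. The 48 h medians with this rescaling were 1.0 for antigen presentation, 0.68 for cytokines and 0.71 for NF-κB genes, and -0.61, -0.64 and -0.75 for osteoblast, fibrillar matrix and Wnt genes. With 9.8 prior degrees of freedom in the additive fit, 5 chemokine genes, 4 NF-κB genes, 2 antigen presentation genes and 1 cytokine gene rose, and 4 osteoblast and 2 fibrillar matrix genes fell. Of the lymphotoxin receptor pathway, matrix protease, adipocyte and cell cycle inhibitor lists 1 gene each rose there, and 0 genes passed in each other list with at least 3 tested genes, Wnt and lymphoid-tissue stromal genes among them.

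**Figure D4:**
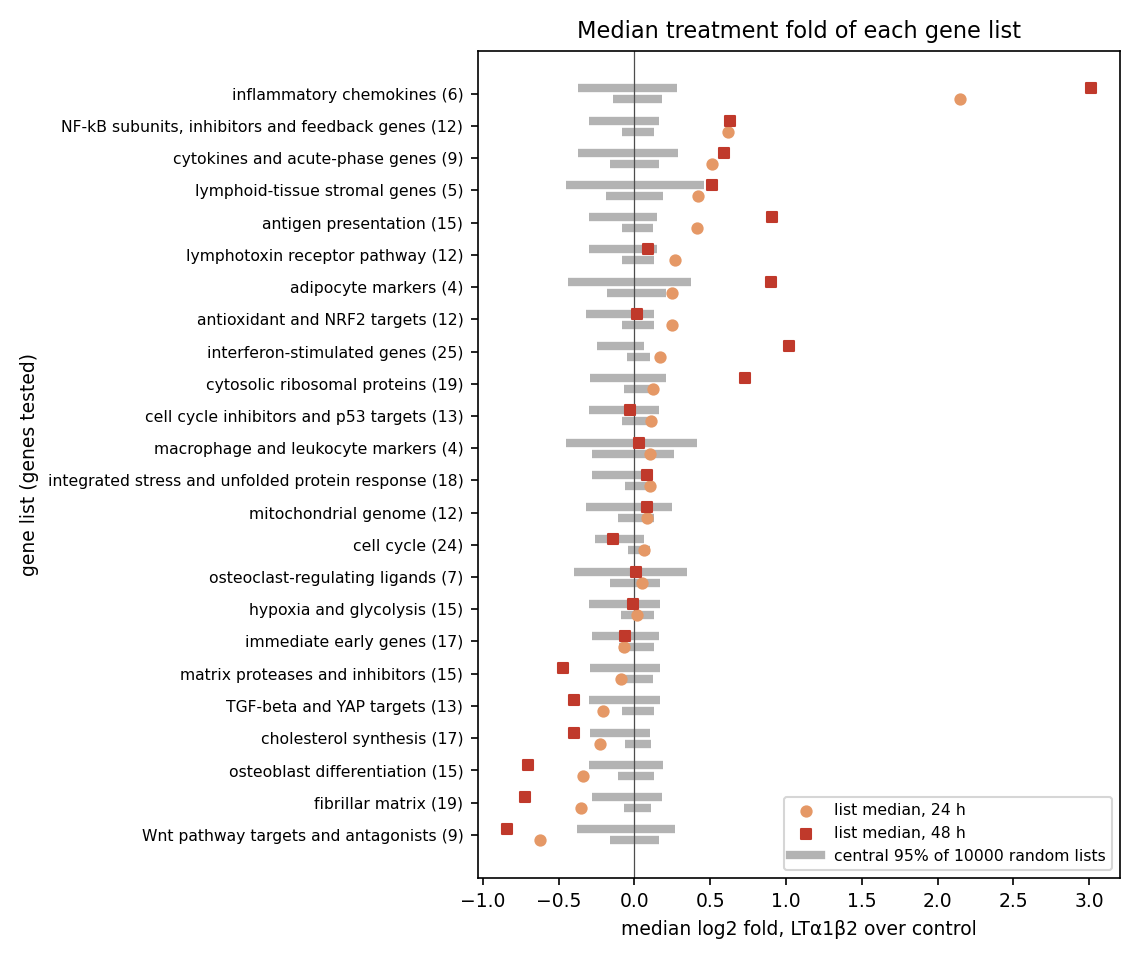
Median log2 fold of LTα1β2 over control in each gene list with at least 3 tested genes, circles for 24 h and squares for 48 h, with the number of tested genes in brackets. Grey bars hold the central 95% of 10000 random lists matched on mean expression; the chemokine medians of 2.15 and 3.01 and the Wnt medians of -0.62 and -0.84 are the ends of the range.

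Most other lists had medians near 0. In the cell cycle list 0 of 24 genes passed the test, 0 adjusted over the list alone, 0 at an unadjusted limma p below 0.05 and 0 with limma voom. With the length trend removed 1 rose and 2 fell at infinite prior degrees of freedom, and 0 passed at that fit's own estimate. The medians of the list were 0.06 and -0.14. Fas was the only 1 of 13 cell cycle inhibitors and p53 targets that rose (1.74-fold and 2.36-fold), against 2 adjusted over the list alone, and 3 rose and 1 fell without the treated 48 h library. Of 18 genes of the integrated stress and unfolded protein responses (medians 0.10 and 0.08) and of 15 hypoxia and glycolysis genes (0.02 and -0.01), 0 passed in limma on either adjustment or with voom, and 2 and 1 had an unadjusted p below 0.05. Without the treated 48 h library or with median-of-ratios rescaling 1 stress-response gene rose. With the length trend removed 2 stress-response genes rose, and 1 hypoxia and glycolysis gene rose and 1 fell. At that fit's own estimate of prior degrees of freedom 1 stress-response gene rose and 0 hypoxia and glycolysis genes passed. The median-of-ratios fit at its own estimate called 0 stress-response genes. The small 48 h medians of both these lists and of the cell cycle inhibitors (-0.03) changed sign under the length correction or median-of-ratios rescaling (-0.05, 0.08 and 0.06). Of 17 immediate early genes Junb rose and Egr3 fell (1 and 2 adjusted over the list alone, over all genes 5 and 0 without the treated 48 h library and 3 and 4 with the length trend removed). With the length trend removed at its own estimate of prior degrees of freedom, 2 immediate early genes rose and 1 fell. Of 12 antioxidant genes the metallothionein genes Mt1 and Mt2 rose, 2 adjusted over the list alone. With the length trend removed 4 antioxidant genes rose, and 1 at that fit's own estimate. The median of this list was not near 0 at 24 h, at 0.25 against a random range of -0.08 to 0.13. At 48 h it was 0.02 (-0.32 to 0.13). Of 7 ligands that regulate osteoclasts Il34 rose, 1 adjusted over the list alone. With the length trend removed 2 rose and 1 fell, and 0 passed at that fit's own estimate. Tnfrsf11b, the decoy receptor osteoprotegerin, was at 0.862 (0.807 to 0.92) and 0.818 (0.758 to 0.882) of control (adjusted p = 0.511, limma).

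The ribosomal protein list, all 19 genes higher at both times, had medians of 0.12 at 24 h and 0.73 at 48 h, and 0.46 at 48 h with the length trend removed. Of these 2 rose, Rps14 (1.13-fold and 2.89-fold) and Rps3 (1.19-fold and 2.36-fold), and 12 adjusted over the list alone. At infinite prior degrees of freedom 7 rose with the length trend removed and 9 with median-of-ratios rescaling (48 h median 0.81). At the own estimates of these fits 1 and 0 rose. At 24 h, where the treated 48 h library was not used, 0 genes of the list were at least 2-fold higher, against 3 at 48 h. Of 12 mitochondrially encoded genes 1 rose, mt-Nd3 (limma log2 fold 0.63 ± 0.21 SE), 1 adjusted over the list alone and with median-of-ratios rescaling, and 0 without the treated 48 h library or with the length trend removed. The 48 h median of this list was 0.08, and -0.17 with the length trend removed. The median-of-ratios fit at its own estimate of prior degrees of freedom called 0 of the mitochondrially encoded genes. The mitochondrial share of CPM was 3.11% and 3.37% in control and 3.31% and 3.45% in treated cells.

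Marker lists of other cell types were mostly outside the tested genes. Of 11 macrophage and leukocyte markers 4 were tested and 0 rose or fell in limma over all genes, 0 with voom and 1 each adjusted over the list alone, with median-of-ratios rescaling and at an unadjusted p below 0.05, with medians of 0.10 and 0.03. Cd14 gave log2 folds of 0.52 and 0.50 and Csf1r, at 1.56 CPM or less in every library, -0.46 and -0.21. Of 13 adipocyte markers 4 were tested and 2 rose, Cebpd (1.92-fold and 2.59-fold) and Fabp4. The medians of the 4 were 0.25 at 24 h and 0.90 at 48 h, against random ranges of -0.18 to 0.21 and -0.44 to 0.37. The count was 3 adjusted over the list alone, and 3 with the length trend removed or with median-of-ratios rescaling. At the own estimate of prior degrees of freedom of each of these fits it was 1. The median-of-ratios fit at its own estimate called 0 macrophage and leukocyte markers. Fabp4 was 1.24-fold at 24 h (0.745 to 2.07), not detectable as a difference at this depth, and 4.61-fold higher at 48 h (2.76 to 8.08). Lists with fewer than 3 tested genes give values only: the chondrocyte genes Sox9 (-0.09 and -0.29) and Col2a1 (-0.47 and -0.70), the endothelial gene Flt1 (0.42 and 0.14), the muscle genes Des (-0.34 and -0.04) and Tnnt2 (0.20 and 0.17) and the histone genes Hist1h1c (-0.17 and -0.06) and Hist1h1d (-0.45 and -0.11). Of the 8 epithelial markers 0 were tested.

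What changed from 24 h to 48 h was asked in each treatment, with more genes passing the 2-fold rule in treated than in control cells. In control 1 gene was at least 2-fold higher at 48 h and 3 were lower. The immediate early gene Egr1 was at 0.437 of its 24 h level (0.397 to 0.481) in control and 0.455 (0.405 to 0.511) in treated cells. The other control genes, named after their values were seen, were Gm15910 (0.330 of its 24 h level), Kifc2 (0.305) and, higher, Fhod3 (2.76-fold), all from a few CPM. In treated cells 127 genes were higher and 52 lower, 70.9% higher, and 207 and 31 with median-of-ratios rescaling, 87.0% higher, which moved the median log2 fold of all genes by 0.13. Egr1 and Gm15910 were 2-fold lower in both treatments, where independent lists would share 0.013. Interferon-stimulated genes had a median log2 change of -0.13 in control and 0.70 in treated cells. Ifit1 was at 0.939 of its 24 h level in control (0.883 to 0.999) and 3.64-fold higher in treated cells (3.48 to 3.82). Ribosomal protein genes had medians of 0.08 and 0.70. The treated time fold declined with transcript length (rho = -0.510, control -0.122), and the count of higher genes was 82 with the length trend removed.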

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

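Genes were sought among those named by rule whose counting intervals lay on opposite sides of 1 at 24 h and 48 h, and 2 were found; the differences were not tested, since each time has 1 library per treatment. Mki67, a marker of cycling cells, had a log2 fold of 0.06 at 24 h (1.04-fold, 95% counting interval 1.01 to 1.08) and -0.62 at 48 h (0.648, 0.623 to 0.674). Its transcript is 10061 bases long, and with the length trend removed the 48 h log2 fold was -0.26. Lyz2, lysozyme, had a log2 fold of -0.19 at 24 h (0.873, 0.794 to 0.959) and 0.20 at 48 h (1.16-fold, 1.05 to 1.27). Its transcript is 1316 bases long, and with the length trend removed the 48 h log2 fold was -0.01. Among all 317 tested list members, named or not, 18 had intervals on opposite sides of 1.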

How the results depend on the processing

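Removal of the transcript-length trend, leaving out libraries, limma voom and other prior degrees of freedom were chosen after seeing the data. Of the 631 genes called in the additive fit, 6 had a fold of the other sign without the treated 48 h library. Of those tested, 0 did under each other alternative to this fit. With no time term, no trend or other prior degrees of freedom the fold is the same by construction. Of 50 folds of 25 named genes, 0 changed sign under 4 settings, and a pseudocount cannot change a sign. Neither checks stability, since the 631 and most of the 25 were picked for large mean folds in the same libraries. The 48 h log2 fold of Lyz2, not among the 25, went from 0.20 to -0.01 with the length trend removed. The 48 h list medians near 0 changed sign in 5 lists, 0.06 against -0.03 being an example for cell cycle inhibitors. However, counts by a rule of size moved widely. Values are given as higher and lower genes, and the counts as reported were 42 and 22 (24 h), 226 and 87 (48 h), 26 and 13 (both times), 1 and 3 (time in control), 127 and 52 (time in treated cells) and 355 and 276 (additive fit). A pseudocount of 5 shrinks the folds of low genes by construction. It gave 19 and 5 at 24 h, 126 and 28 at 48 h, 15 and 5 at both times, 0 and 1 for time in control and 70 and 3 for time in treated cells. List medians with it were 1.65 and 2.40 for chemokines at 24 h and 48 h, 0.28 for cytokines and -0.40 for Wnt genes at 24 h. A pseudocount of 0.25 gave 44 lower genes at 24 h, 156 at 48 h, 22 at both times, 10 higher and 19 lower for time in control and 130 lower for time in treated cells. A mean CPM of at least 5, which tests fewer genes, gave 14 lower at 24 h, 0 and 1 for time in control and 30 lower for time in treated cells. The 1.5-fold rule admits more genes by construction: 180 and 164 at 24 h, 899 and 764 at 48 h, 100 and 98 at both times, 49 and 121 for time in control, 678 and 845 for time in treated cells. Median-of-ratios rescaling gave 207 and 31 for time in treated cells and 95 and 83 in the additive fit; it shifted the median log2 fold of all genes by 0.08 at 48 h and 0.13 for time in treated cells. With the length trend removed, 82 genes were higher with time in treated cells, and the 48 h medians were 0.33 for the lymphotoxin receptor pathway, -0.45 for fibrillar matrix and 0.46 for ribosomal proteins. The fewer calls with median-of-ratios rescaling came from the prior degrees of freedom, estimated as 9.8 against infinite. The 631 genes had a median absolute log2 fold of 0.69 there and 0.68 before, and a median SE of 0.176 in both. With infinite ones, which ignore differences in spread between genes of like level, the rescaled values gave 809 and 459, and with 9.8 the values as deposited gave 39 and 25. A fit with no time term gave 20 and 11 genes, all 31 among the 631, at 6.3 prior degrees of freedom, and 403 and 320 with infinite ones, 598 of them among the 631. Leaving out 1 library, which also drops the time term and so is to be set beside 20 and 11 as well, gave from 16 to 1886 higher and from 6 to 3063 lower genes. With a control library left out, the spread comes from the treated pair alone and the calls were fewest; without the treated 24 h library it comes from the control pair alone, and the lone sample is assumed to vary like them. limma voom called 596 of the 631, a fit without the treated 48 h library 344 and a fit with the length trend removed 425, at 11.1 prior degrees of freedom, or 602 (1044 and 709 in all) with infinite ones. Of 50 folds of named genes, a pseudocount of 5 moved 21 beyond their counting interval, length removal 6 and median-of-ratios rescaling 1.

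An edgeR fit of the recovered reads had been listed beforehand and was not run, since no listed value is below 9 reads and the worth of 1 read was inferred, not seen as a lowest value; limma voom on these reads was run instead. No paired analysis was possible because each group has 1 library and the labels carry no replicate numbers; that is, no replicate block could be fitted, while the time term of the additive fit does set treated against control cells within each time. Depth of 11355974 to 15995777 reads limits low genes: Fabp4 at 24 h had an interval of 0.745 to 2.07.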

Other observations

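Of the genes 2-fold higher at both times, 12 lay outside the fixed lists and the rule for named genes, and 1 of the lower; they are named here after their values were seen and form no tested group. Casp4, which encodes an inflammatory caspase, was 2.30-fold higher at 24 h (1.90 to 2.80) and 5.13-fold at 48 h (4.12 to 6.43). The guanylate-binding protein gene Gbp5 was 2.61-fold (1.77 to 3.92) and 5.42-fold higher (3.32 to 9.28), from 2.38 and 1.53 CPM in control. Il1rl1, which encodes the IL-33 receptor, went from 121 to 259 CPM at 24 h and from 127 to 291 CPM at 48 h. The neighbouring genes Tmem176a and Tmem176b were 2.15-fold and 2.25-fold higher at 24 h and 2.16-fold and 2.08-fold at 48 h. The chromatin protein gene Hmga1 was 2.41-fold and 2.36-fold higher, and the adhesion molecule gene Icam5 2.55-fold and 2.95-fold. Nckap5 was 3.56-fold and 4.79-fold higher, Rnf150 3.05-fold and 2.90-fold, Dtx4 2.36-fold and 2.35-fold, Gm15987 2.73-fold and 2.60-fold and G930009F23Rik 2.80-fold and 3.27-fold. The lower gene, Auts2, was at 0.45 and 0.442 of control. All 12 rose and Auts2 fell in the additive fit (limma), which follows from their choice as 2-fold changed at both times in the same libraries.

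The tests chosen only after their results had been seen were the comparison of interferon-stimulated genes between times in control and treated cells, and the 24 h percentile of the osteoblast and matrix genes with the range of their matched lists. The principal-transcript check of the ribosomal list was added later.

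Genes with short transcripts, ribosomal protein genes among them, were higher in the treated 48 h library than in the others. Sampling from fewer reads is argued against, since among genes with a mean of at least 1000 reads the 48 h fold still declined with length (rho = -0.55). A transcript-length bias of that library, from RNA quality or library preparation, and a biological shift toward short transcripts cannot be told apart. The decline outside the ribosomal, interferon and antigen presentation lists (rho = -0.44) restates the pattern and would be seen under both, and 1 treated library at 48 h was used here. Ribosomal protein genes may be raised beyond that, with a median at percentile 99.9 of lists matched on length and level, but with principal-transcript lengths the percentile was 97.97, with the median of 0.73 just above a random range of 0.22 to 0.72. The random lists were not barred from drawing ribosomal protein genes themselves, so both percentiles are set against a pool that holds such genes.

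Interferon-stimulated genes had a higher fold at 48 h than at 24 h, when their median of 0.17 already lay above the random range (-0.05 to 0.1). The length trend of the treated 48 h library is argued against as the whole cause, since their 48 h median log2 fold was 1.0 with the trend removed and 1.02 with it. The same genes had a median change of -0.13 from 24 h to 48 h in control cells, so time in culture alone did not raise them there. A late or growing interferon response to LTα1β2 is a hypothesis that cannot be told apart from a property of the single treated 48 h culture, because no other treated library of that time was used here.

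Osteoblast differentiation and fibrillar matrix genes were lower at both times. The length trend of the treated 48 h library is argued against as the whole cause, since at 24 h, where that library was not used, the median of the 34 genes was at percentile 0 of lists matched on length and level. A length trend in the treated 24 h library is argued against too, since those matched lists had 24 h medians from -0.05 to 0.09, against -0.35. At 48 h the median went from -0.71 to -0.49 with the trend removed, so part of the 48 h size may come from it. Lower expression of this programme with LTα1β2 is a hypothesis, found and tested on the same data, and a difference between the cultures other than treatment stays open at each time.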
